A study of Mus musculus with 8 samples.

How the data were processed

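The series holds 8 Affymetrix single-colour arrays of sorted mouse tumour cells, 4 from WD-SCC and 4 from PD-SCC. Per the labels' protocols, tumour cell suspensions were depleted of blood and endothelial cells before sorting, RNA was extracted with Trizol and biotin-labelled cRNA was hybridised. The deposited values are 1 log2 value per probe set and array; the submitters' processing notes name the affy package and RMA, which corrects background, normalises quantiles between arrays and summarises probes. Versions, the chip definition and which arrays were normalised together are not given in the sources used here. The log2 scale was read from the values, which lie between 2.40 and 13.2 on all arrays. Scanner files were not used here, so the background correction could not be redone.

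Groups and lineages came from the labels, which write the later stage as PD/S-SCC, shortened here to PD-SCC. Replicate numbers in the labels count arrays within a lineage and stage, and 1 OT7 WD-SCC array has no number, so arrays were paired by lineage, which the series design says passed from WD-SCC to PD-SCC. Deviations from the stage means correlated across genes at -0.04, 0.02 and 0.06 between the stages of OT7, OT14 and OT15, so the pairing comes from the labels and the values themselves show none of it.

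Probe sets were named through the platform annotation, with symbols updated by Entrez number through a RefSeq gene table (99.3% of genes matched). Of 45141 probe sets, 104 were controls, 28898 had 1 gene symbol, 551 several and 15588 none. Each gene was represented by its probe set with the highest mean over the 8 arrays, which left 17098 genes. The tests used R 4.3.3 and limma 3.58.1, and plots used Python 3.11.15 with matplotlib 3.10.9.

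The stage effect was fitted with limma (lmFit and eBayes, two-sided) with lineage as a fixed block, leaving 4 residual degrees of freedom. Adjusted p are Benjamini-Hochberg values and the threshold was 0.05. The effects within lineages and their difference came from a fit with 1 coefficient per lineage and stage, whose 2 residual degrees of freedom come from the OT7 arrays alone. The lineage difference was the F test of the 2 lineage coefficients beside stage. A gene at or under the highest of the 15 unspiked bacterial control probe sets on each array of 1 stage has a bound in place of a fold, computed from the bright stage's mean and, for each array of the dim stage, the higher of the control and the gene.

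The 23 gene lists held 572 symbols, of which 45 had no probe set of 1 gene. They were tested with camera (preset correlation 0.01), with camera with an estimated correlation and with fry, and adjusted over the lists. Each list's median was also set against 10000 random lists matched on mean level in 100 bins. The lists, the tests of the 3 comparisons and of the lists, and the rule for named genes were fixed before the data were examined. The rule took the 6 largest rises and 6 largest falls past the threshold with 1 sign in every lineage, up to 3 genes per list with the smallest p, the 5 smallest p of the interaction and of the lineage difference, and Itga6, Cd34, Krt5, Krt14, Cdh1, Vim, Egfr, Fgfr1 and Pdgfra whatever their values. Genes named outside it were chosen with their values or their role as markers in view. They are Krt8, Ptprc, Tek, Eif2s3y, Kdm5d, Uty, Cdkn2a, Cdkn2b, Mtap, Psors1c2 and others of the closing part.

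The fits were tested on simulated data for the 17098 genes. The stage fit recovered 56.2% of genes changed by a log2 value of 1, 86.1% of those changed by 2 and 98.2% of those changed by 4, and 5.59% of its calls were false. Camera called 20 of 20 shifted simulated lists and 0 of 20 unshifted ones. Those simulated genes varied independently, so the test does not cover genes that vary together. The simulated arrays also varied independently, and in the stage test a changed gene moved alike in every lineage. The rates thus do not cover stage effects that differ between lineages, or arrays of 1 lineage that vary together. They are not the error rates of the real calls.

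The alternatives were no block, lineage as a random block, averaged OT7 arrays, a paired test on lineage means, a filter on dim genes, the mean of a gene's probe sets, all probe sets, cyclic loess, scaling to the 75th percentile, a trended and robust prior, array weights, a fold threshold of 2 and leaving out each array or lineage. A filter keeping 4734 genes with a mean of at least 6 in the brighter stage, and the interaction without lineage OT15, were chosen after seeing the data.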

Results

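Gene expression was measured in tumour cells sorted from serially transplanted mouse skin squamous cell carcinomas (SCC), a cancer of the keratinocytes of the skin. The cells carried α6-integrin and CD34 on their surface, and the labels call them cancer stem cells. Per the series design, tumours of K14-HPV16 mice, which express papillomavirus genes in basal keratinocytes, were grafted onto immunodeficient mice and passed on until well differentiated SCC (WD-SCC) became poorly differentiated (PD-SCC). The sample labels write the later stage as PD/S-SCC, which is shortened to PD-SCC here. Cells of both stages came from 3 tumour lineages, OT7, OT14 and OT15. OT7 gave 2 arrays per stage and each of the others gave 1, so that 4 WD-SCC arrays stood against 4 PD-SCC arrays. The labels number the arrays as biological replicates, without saying whether the 2 OT7 arrays of a stage came from separate tumours, so p-values measure the spread between these samples, which may in part be technical. The number of arrays limits the precision.

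All 8 arrays carried 45141 probe sets, and 17098 genes had a probe set of their own. Values are log2 units throughout. Array medians lay between 3.66 and 3.77. The highest of the 15 bacterial control probe sets without a spike averaged 4.11 on the WD-SCC arrays and 3.69 on the PD-SCC arrays, and a gene at or under it on every array of a stage is given as a bound. Across genes, which are not independent replicates, arrays of different stages correlated at 0.815 to 0.884, WD-SCC arrays with each other at 0.909 to 0.950, and PD-SCC arrays with each other at 0.941 to 0.979. The first principal component held 56.8% of the variance and separated the stages.

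The first comparison asked how the sorted cells differed between PD-SCC and WD-SCC within lineages. Of the genes past the threshold with the same sign in each lineage, the 6 that fell furthest were Lce3a, Sprr2d, Sprr2f, Dmkn, Psca and Dsp. Lce3a, a late cornified envelope gene, was at least 297-fold lower in PD-SCC (WD-SCC 11.91 ± 0.51, PD-SCC 3.34 ± 0.23, mean ± SD, n = 4, adjusted p = 9.95e-05, limma). Dmkn, a secreted keratinocyte gene, was at least 207-fold lower and the small proline-rich gene Sprr2f at least 177-fold lower. Sprr2d fell by 8.16, Psca fell by 7.53 and Dsp, which encodes desmoplakin, fell by 7.49 on the log2 scale, the last with an SE of 0.17 and an adjusted p of 9.21e-05. The largest rises were those of Gfra2, a GDNF family co-receptor, from 4.27 ± 1.16 to 10.68 ± 0.58 (log2 difference 6.41 ± 0.54 SE, adjusted p = 0.00405), Crabp1, a retinoic acid binding protein (5.22 ± 0.69, adjusted p = 0.0106), the water channel gene Aqp1 (4.59 ± 0.87, adjusted p = 0.0277), S100a4 (4.26 ± 0.27, adjusted p = 0.00171), Aldh3a1 (4.15 ± 0.91, adjusted p = 0.0397) and the mitotic gene Cenpf (4.07 ± 0.39, adjusted p = 0.00523). Aldh3a1 and Aqp1 differed most in OT7, Aldh3a1 by 6.25 there, 2.12 in OT14 and 1.99 in OT15, and Aqp1 by 6.45, 3.35 and 2.12, although the test of a difference between the lineages' stage effects was not past the threshold (adjusted p = 0.236 and 0.359). Some of these 12 genes were above the bacterial controls on only part of the dimmer stage's arrays: Gfra2 and Cenpf on 2 of 4, Crabp1, Aqp1 and S100a4 on 3, and Sprr2d, Psca and Dsp on 1. Of other genes given with a difference, that number was 1 for Cldn4 and Fabp4, 2 for Rab25 and S100a8, and 3 for Cdsn, Il1rn, Lama3, Mmp13, Birc5 and Mgp.

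Of the 17098 genes, 2154 differed between stages at an adjusted p under 0.05 (limma with lineage as a block, two-sided), 1331 of them higher and 823 lower in PD-SCC. All 2154 had the same sign in each lineage, which the test favours, while of all 17098 genes 65.4% had the same sign in OT7 and OT14, 68.8% in OT7 and OT15 and 68.3% in OT14 and OT15. Changes of at least 16-fold were mostly falls, with 106 lower genes and 6 higher ones. The count rested on treating the OT7 arrays as separate replicates: with them averaged it was 401 (202 higher, 199 lower), without lineage OT7 it was 247 (53 higher, 194 lower), and with a paired test on the 3 lineage means no gene passed, with 2574 at an unadjusted p under 0.05. The split between higher and lower genes also depended on the scaling, since cyclic loess gave 799 higher and 930 lower, and scaling to the 75th percentile gave 1150 higher and 1205 lower with a median over all genes of -0.21 in place of -0.06.

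Leaving out an OT14 or OT15 array takes its whole lineage out of the stage effect, since the lineage block absorbs the array that is left. Without either OT15 array, and so without OT15, 1282 genes passed. Without either OT14 array, and so without OT14, 1240 did. Without the OT7 WD-SCC array numbered 2 there were 1198, and without 1 or the other OT7 PD-SCC array 886 or 906. Of the 70 named genes past the threshold, 45 stayed past it without any 1 array. Aldh3a1 was not among them, with adjusted p of 0.0508 to 0.114 when an array was left out, and neither was Aqp1, whose adjusted p was 0.0839 without the OT7 PD-SCC array numbered 1.

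All 3 epithelial gene groups were lower in PD-SCC by camera with its preset correlation (adjusted p = 2.81e-13, 9.22e-14 and 4.88e-10 in the order given here). The first held with an estimated correlation (adjusted p = 0.0419 with an estimated correlation), and the other two did not (adjusted p = 0.241 and 0.25 with an estimated correlation). Of 32 measured genes of the cornified envelope and terminal differentiation, 19 fell and none rose, with a median of -3.45 (21 fell when adjusted over the list alone). Cdsn, which encodes corneodesmosin, fell by 6.72 (adjusted p = 0.000585) and Sprr1b was at least 45.1-fold lower (adjusted p = 0.000622). Of 30 genes of epithelial keratins and epithelial identity, 20 fell and none rose (25 adjusted over the list alone). They included the basal keratin gene Krt5, from 11.26 ± 0.49 to 4.16 ± 0.17 (adjusted p = 9.11e-05), Rab25, which fell by 5.08, and Epcam, an epithelial adhesion gene, which fell by 4.62. Krt8 of the same list went the other way in OT7 and OT14, short of the threshold over all lineages (log2 difference 3.06, adjusted p = 0.23). It differed by 5.73 in OT7, 3.77 in OT14 and -3.01 in OT15. Of 23 genes of desmosomes, tight junctions and adherens junctions, 14 fell (16 fell and 1 rose adjusted over the list alone). The tight junction gene Cldn4 fell by 7.37 and the desmosomal cadherin gene Dsc3 fell by 2.04.

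With values under the bacterial controls raised to them, the medians of these 3 groups were -3.18, -1.77 and -2.04. Nonspecific control probe sets with 25 G and C bases were brighter on the WD-SCC arrays, at 8.39 ± 0.26 against 6.94 ± 0.19 (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0762 over 8 array measures).

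**Figure D1:**
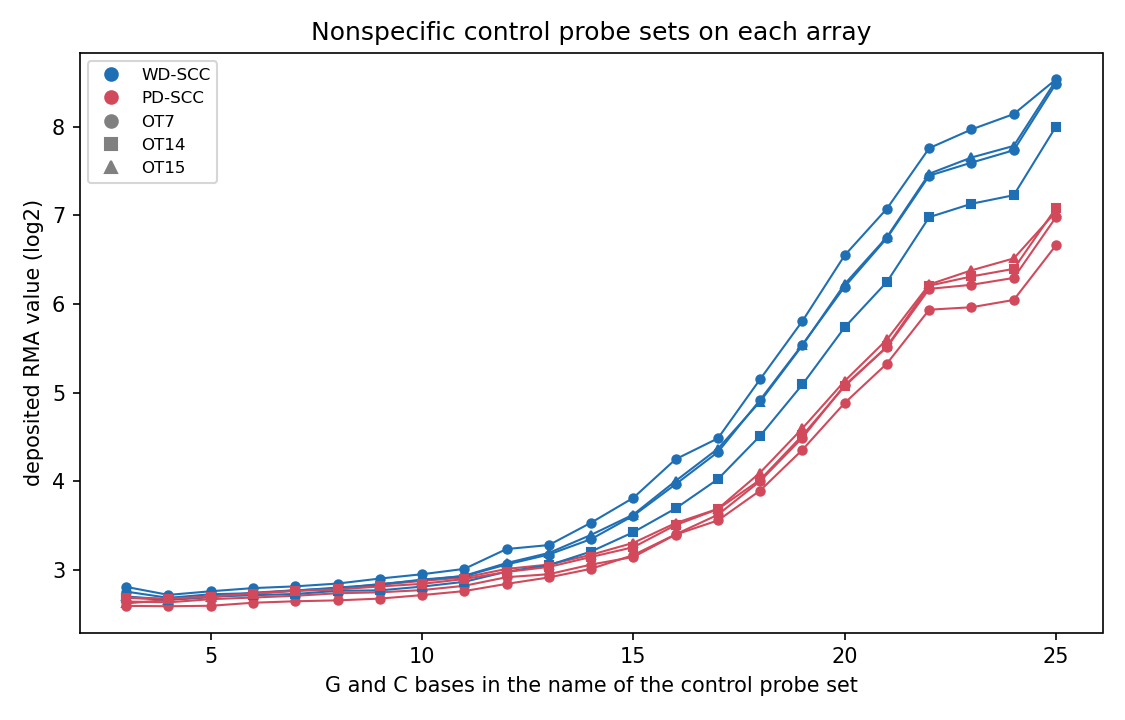
Deposited log2 values of the 23 nonspecific control probe sets on each of the 8 arrays, against the number of G and C bases in the control's name; each line is 1 array, coloured by stage, with the marker giving the lineage. The WD-SCC arrays lie above the PD-SCC arrays at high G and C content, with means of 8.39 and 6.94 at 25 bases.

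Cell cycle genes were higher in PD-SCC. Of 34 measured members, 19 rose and none fell, with a median of 1.47 (28 rose and 1 fell adjusted over the list alone). Birc5, which encodes survivin, rose from 4.18 ± 0.28 to 6.37 ± 0.49 (adjusted p = 0.0019), the spindle gene Tpx2 rose by 3.14 (adjusted p = 0.00204) and the cyclin gene Ccna2 by 3.04 (adjusted p = 0.00307). The camera adjusted p was 5.37e-13, and the call held with an estimated correlation (adjusted p = 0.0419 with an estimated correlation).

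The list of epithelial to mesenchymal transition factors and mesenchymal genes was also higher, with 7 genes up and 1 down among 26 (11 up and 1 down adjusted over the list alone) and a median of 0.81. The camera adjusted p of 0.00118 was lost with an estimated correlation (adjusted p = 0.25 with an estimated correlation) and with fry (adjusted p = 0.0541). It was also lost with the filter on a mean of at least 6 in the brighter stage, chosen after seeing the data (camera adjusted p = 0.132). S100a4 rose as given above, the transcription factor gene Snai1 rose by 0.66 ± 0.09 SE (adjusted p = 0.0116, and 0.0559 without the lineage block), and Thy1, a surface glycoprotein gene of fibroblasts and other cells, fell by 3.92 (adjusted p = 0.00081). Of 31 genes of extracellular matrix and collagens, 3 rose and none fell (2 and 0 adjusted over the list alone), among them the fibronectin gene Fn1 by 1.95 (adjusted p = 0.0118), but the list itself was not past the threshold (camera adjusted p = 0.216, and 0.0422 without the unnumbered OT7 WD-SCC array). Of 24 fibroblast markers, 2 rose, Crabp1 and Mgp (Mgp adjusted p = 0.0175, and 0.0562 without OT15), and none fell (5 and 3 adjusted over the list alone). The fibroblast list had a median of -0.21, while camera pointed up, with an adjusted p of 0.933.

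**Figure D2:**
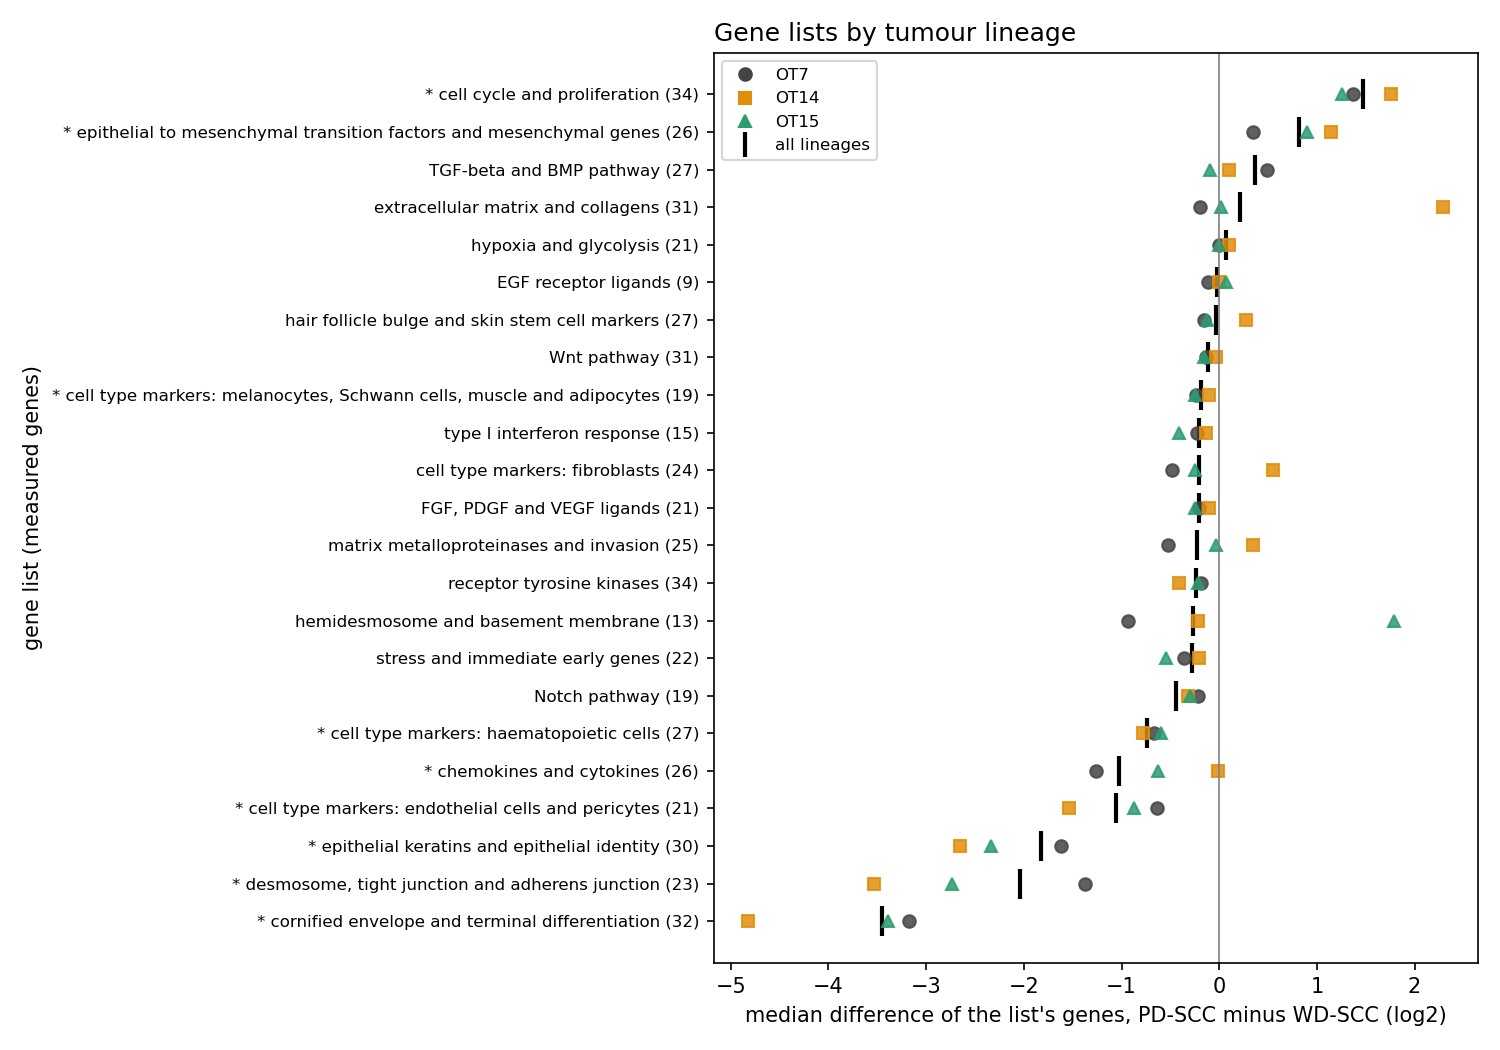
Median log2 difference between PD-SCC and WD-SCC of the measured genes of each of the 23 lists, with 1 marker per lineage and a bar for the fit over all lineages; an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Cell cycle genes lie above 0 in each lineage, with an overall median of 1.47, and cornified envelope genes lie furthest below 0, at -3.45.

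Some markers of other cell types were lower in PD-SCC, haematopoietic and endothelial ones among them, although the suspensions had been depleted of blood and endothelial cells. Camera gave adjusted p of 3.13e-06, 5.33e-05 and 0.00491 for the 3 lists in the order given here, and none held (adjusted p = 0.25, 0.404 and 0.25 with an estimated correlation). Of 27 haematopoietic markers, 7 fell and none rose (8 and 0 adjusted over the list alone), with a median of -0.74. They included S100a9 and S100a8, which are abundant in neutrophils and also made by activated keratinocytes, of which S100a9 fell by 5.95 (adjusted p = 0.00224) and S100a8 fell by 6.14 (adjusted p = 0.00432), and the macrophage gene Cd68, which fell by 2.79 (adjusted p = 0.0141). Of 21 endothelial and pericyte markers, 5 fell and none rose (7 and 0 adjusted over the list alone), of which the claudin gene Cldn5 fell by 1.19 (adjusted p = 0.00951). Among 19 markers of melanocytes, Schwann cells, muscle and adipocytes, Fabp4, the fatty acid binding protein gene of adipocytes, fell by 3.89 and Ckm fell by 0.57 (adjusted p = 0.0309, and 0.0978 without the OT7 PD-SCC array numbered 1), with none rising (2 and 0 adjusted over the list alone).

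The median of the last list was -0.19, at percentile 8.06 of 10000 random lists matched on expression. Some lists that camera did not call lay lower. The percentile was 0.01 for the Notch pathway, 0.05 for stress genes, 0.12 for matrix metalloproteinases and 0.19 for receptor tyrosine kinases. It was 1.28 for hemidesmosomes and 1.38 for fibroblast markers. The other uncalled lists lay between 5.38 and 93.37. Among 26 chemokines and cytokines, 3 fell and none rose (6 and 0 adjusted over the list alone). The camera adjusted p of that list was 0.00379, lost with an estimated correlation (adjusted p = 0.47 with an estimated correlation) and with fry (adjusted p = 0.0664). Il1rn, the interleukin 1 receptor antagonist gene, fell by 6.22 (adjusted p = 0.00135) and Il1a was at least 2.43-fold lower (adjusted p = 0.0122).

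The number of called lists was 9, 2 higher and 7 lower. Other groupings of the same arrays often called as many, since 14 of the 34 splits that could be fitted, the real one included, gave 9 or more lists and the highest gave 13. Of the 12 splits that part each lineage evenly, 5 did, and the highest other gave 12. Such splits can still set the stages against each other within some lineages, so these counts do not measure chance.

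No signalling list was past the threshold by camera, and single members rose or fell. Fry, which tests whether a list's genes move one way and does not compare them with other genes, was past it, downward, for EGF receptor ligands (adjusted p = 0.00478), receptor tyrosine kinases (adjusted p = 0.00796) and the Notch pathway (adjusted p = 0.0128). Of 34 receptor tyrosine kinases, 1 rose and 5 fell (2 and 7 adjusted over the list alone, camera adjusted p = 0.13, and 0.0321 with the filter on dim genes), of which Ephb3 fell by 3.86 (adjusted p = 0.00871). Among 9 EGF receptor ligands, Tgfa fell by 4.46 (adjusted p = 0.00118), Nrg2 fell by 0.73 (adjusted p = 0.015, and 0.0565 without the OT7 PD-SCC array numbered 2) and Ereg rose by 1.95 (adjusted p = 0.0283, and 0.0568 without OT15), with 2 and 2 adjusted over the list alone and a camera adjusted p of 0.664, or 0.0412 with the filter at 6 that was chosen after seeing the data. Of 21 FGF, PDGF and VEGF ligands Pdgfc rose and none fell (adjusted p = 0.0402, and 0.0648 without OT15 and 0.0513 without the lineage block; 0 adjusted over the list alone, camera adjusted p = 0.404). Of 27 genes of the TGF-beta and BMP pathway, 4 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.26). The BMP antagonist gene Grem1 rose by 2.49 (adjusted p = 0.0056), Ltbp2 was at least 6.77-fold higher (adjusted p = 0.00716), and Id2, a target of BMP signalling, fell by 1.73 (adjusted p = 0.00471).

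Of 31 Wnt pathway genes, 2 rose and 2 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.607), and of 19 Notch pathway genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.0919, and 0.033 without the OT7 WD-SCC array numbered 2). Rbpj, the DNA-binding partner of Notch, rose by 2.46 (adjusted p = 0.00635). Of 27 markers of the hair follicle bulge and skin stem cells, 2 rose and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.729), with a median of -0.04 although the mean was 0.17. Of 13 genes of hemidesmosomes and basement membrane, 3 rose and 3 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.933). The laminin genes Lama3 and Lamc1 went apart: Lama3 fell by 4.86 (adjusted p = 0.00336) and Lamc1 rose by 1.42 (adjusted p = 0.0105). Without either OT15 array that list was lower, with a median of -0.96 and an adjusted p of 0.0414.

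Of 25 matrix metalloproteinase and invasion genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.404, and 0.0395 with the filter at 6). The collagenase gene Mmp13 fell by 2.34 (adjusted p = 0.0063, and 0.0994 without the lineage block) and Adam8 fell by 3.46 (adjusted p = 0.00944, and 0.0513 without the lineage block). Of 22 stress and immediate early genes, 1 rose and 5 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.293, and 0.0219 with the filter at 6), of which Atf3 fell by 1.96 (adjusted p = 0.00183). Among 21 genes of hypoxia and glycolysis, 1 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.933), of which Ndrg1 fell by 2.74 (adjusted p = 0.00988). Their median was 0.07 and their mean -0.10. None of 15 genes of the type I interferon response passed, over all genes or adjusted over the list alone (camera adjusted p = 0.517, and 0.0158 without the OT7 PD-SCC array numbered 2).

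Over all lineages the sorting markers were not past the threshold between stages. Itga6, which encodes α6-integrin, measured 7.25 ± 1.31 in WD-SCC and 6.95 ± 0.73 in PD-SCC (adjusted p = 0.796). Cd34 measured 6.04 ± 1.65 and 7.71 ± 0.84 (adjusted p = 0.241). On the OT15 WD-SCC array Cd34 stood at 3.58, under that array's highest bacterial control of 4.37, although its cells were sorted as CD34 positive, and the other 3 WD-SCC arrays lay between 6.72 and 7.002. Within lineages the difference of Itga6 was -1.67 in OT7, -0.40 in OT14 and 2.53 in OT15 (adjusted p = 0.0379, 0.791 and 0.0680), and that of Cd34 was 0.21, 1.09 and at least 4.35 (adjusted p = 0.645, 0.366 and 0.0382). OT14 and OT15 have 1 array per stage and take their spread from the OT7 arrays, and the values of OT15 rest on the WD-SCC array that stood apart in Cd34. The lineages were not shown to differ, since the test of a difference between their stage effects gave adjusted p of 0.184 and 0.186.

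Of the remaining genes chosen whatever their values, Krt14, the partner keratin of Krt5, fell from 10.74 ± 0.38 to 5.73 ± 1.45 (adjusted p = 0.00764), and the E-cadherin gene Cdh1 was at least 4.31-fold lower (adjusted p = 0.00219). Vim, a mesenchymal filament gene, differed by 1.03 ± 0.29 SE (adjusted p = 0.0738, and 0.0163 without the unnumbered OT7 WD-SCC array). The difference was -0.88 for Egfr (adjusted p = 0.0667, and 0.0295 without the OT7 WD-SCC array numbered 2) and 0.65 for Fgfr1 (adjusted p = 0.335). Pdgfra lay at or under the bacterial controls on all 4 WD-SCC arrays (measured mean 3.47 ± 0.35) and measured 4.12 ± 0.18 in PD-SCC (adjusted p = 0.0813).

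**Figure D3:**
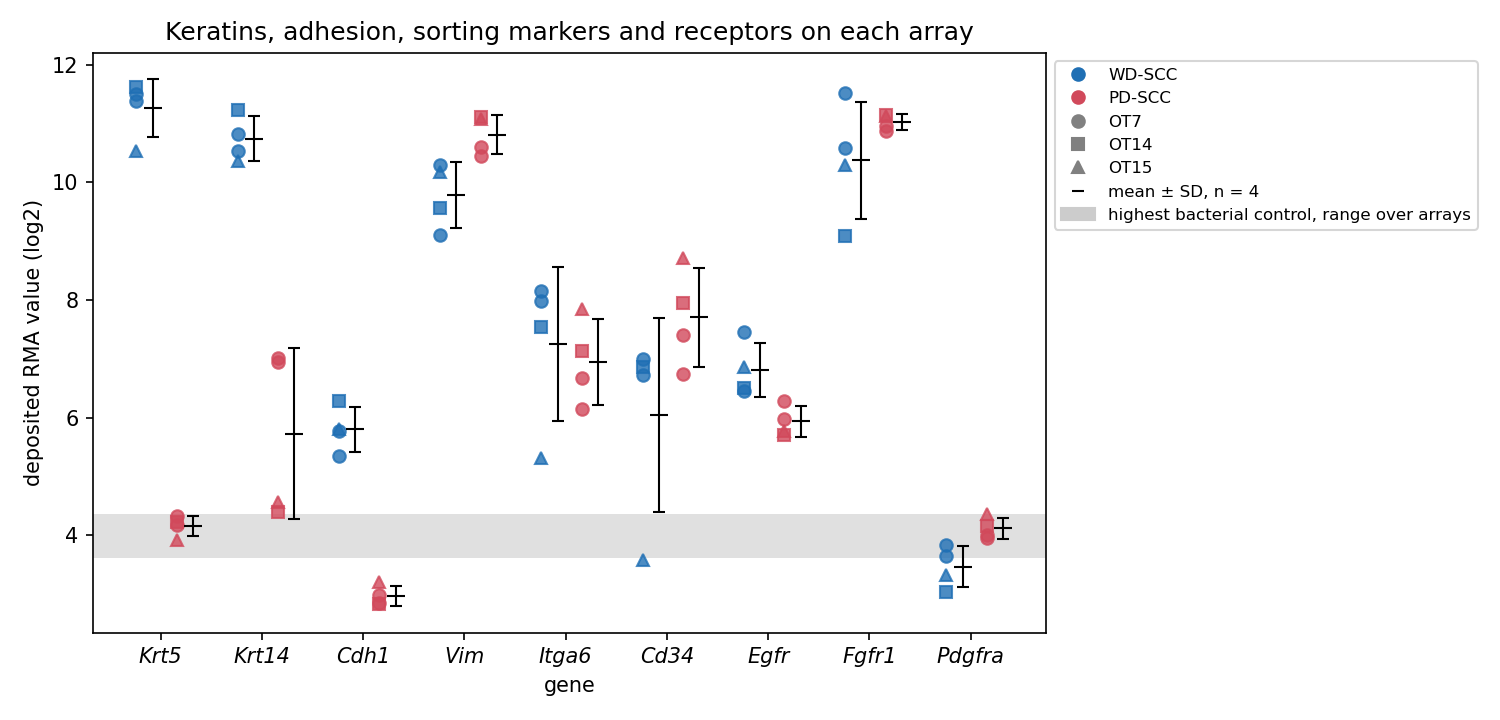
Deposited log2 values of the 9 genes chosen whatever their values, on each of the 8 arrays; colour gives the stage, the marker shape the lineage, black bars the mean ± SD of 4 arrays, and the grey band the range of the highest bacterial control over arrays. Krt5 lies at 11.26 ± 0.49 in WD-SCC and 4.16 ± 0.17 in PD-SCC, and Cd34 of the OT15 WD-SCC array lies at 3.58.

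The next comparison asked how far the lineages shared the stage effect. Krt5 differed between PD-SCC and WD-SCC by -7.19 in OT7, -7.40 in OT14 and -6.60 in OT15, and Ccna2 by 3.46, 2.94 and 2.32. Within OT7, 1061 genes were higher and 490 lower in PD-SCC, within OT14 31 and 113, and within OT15 96 and 131. In all 3 lineages 12 genes were higher and 65 lower. The spread of OT14 and OT15 was that of the OT7 arrays. Across genes, which are not independent replicates, the stage effects correlated at 0.610 between OT7 and OT14, 0.580 between OT7 and OT15 and 0.748 between OT14 and OT15.

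No gene passed the test of a difference between the lineages' stage effects (limma F test, 2043 at an unadjusted p under 0.05, smallest adjusted p 0.181). With a trended and robust prior 14 genes passed. The 5 genes with the smallest p were Nppc, a natriuretic peptide gene, with PD-SCC minus WD-SCC differences of -3.94 in OT7, 3.58 in OT14 and 1.07 in OT15, Rdh10 (2.42, -0.54 and -3.87), Rbpms (-5.29 or lower, 0.33 and 0.06), Xist, the RNA of the inactive X chromosome (0.29, 0.94 and 5.08 or more), and Dlk1. The bounds stand where the dimmer stage lay at or under the bacterial controls. Dlk1 lay at or under them on every array but the OT14 PD-SCC array, where it stood at 9.88, so that only OT14 has a difference, 6.05 or more. In tests on simulated changes between lineages, 2.03% of genes with a log2 difference of 2 were recovered and 75.4% of those with a difference of 4.

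The last comparison asked how much tumours of different lineage differed at equal stage. The 5 genes with the smallest p were Fkbp5, a glucocorticoid-induced co-chaperone gene, with -0.99 in OT14 and -1.90 in OT15 relative to OT7, Saal1 (-1.59 and -1.67), Ahcyl2 (-0.39 and -1.20 or lower, as both OT15 arrays lay at or under the bacterial controls), the activin antagonist gene Fst (-0.98 and -2.95) and Fbxo11 (1.71 and 0.44, with 2 of 4 OT7 arrays and 1 of 2 OT15 arrays above those controls). None of them, and no other gene, passed (limma F test, 1251 at an unadjusted p under 0.05, smallest adjusted p 0.353). Without the OT14 WD-SCC array 2 genes passed.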

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

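The tests of nonspecific background, of fibroblasts in the PD-SCC arrays and of male cells, RNA quality and the stage label of the OT15 WD-SCC array, and the comparison of list effects between lineages, were chosen after the results were seen. A sample far from the 3 others of its stage was looked for in 196 sets of 4 values, and 7 were found (3.57%, where chance gives about 5%). Sprr2d was low on the unnumbered OT7 WD-SCC array, at 9.84 against 11.86 to 12.26 on the others. S100a8 was high on the OT15 PD-SCC array, at 5.06 against 3.38 to 3.62. Dlk1 stood at 9.88 on the OT14 PD-SCC array and at 3.33 to 3.56 on the other PD-SCC arrays. The actin 3' minus 5' difference was -0.50 on the OT15 PD-SCC array against -0.67 to -0.65, and the nonspecific control with 25 G and C bases was 8.002 on the OT14 WD-SCC array against 8.49 to 8.53.

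The remaining outlying values, Cd34 at 3.58 (others 6.72 to 7.002) and Xist at 4.01 (others 9.36 to 9.91), belong to the OT15 WD-SCC array, and Xist on the OT15 PD-SCC array was 9.45. On it 1 of 7 probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty, a probe set of Eif2s3y at 5.47, lay above the 3.31 to 3.90 of the other 7 arrays by more than their range, which is what male cells could give, and a probe set of Uty (3.63 against at most 3.30) and a probe set of Kdm5d (3.89 against at most 3.62) were highest there by less than that range, under the array's highest bacterial control of 4.37, while the other 4 lay no higher than on other arrays. Poor RNA is argued against, since 0 of the 2 differences between 3' and 5' probe sets, of actin and Gapdh, lay outside the range of the other arrays. PD-SCC cells under its label are argued against, since its lowest correlation across genes with another WD-SCC array, 0.909, was above its highest with a PD-SCC array, 0.848, and Krt5 and Lce3a stood at 10.53 and 12.29 on it. Male cells stay open, and the labels give no sex to set them against. WD-SCC cells of OT7 or OT14 under its label stay open and were not tested. The WD-SCC arrays of those lineages had Xist at 9.36 to 9.91 and Cd34 at 6.72 to 7.002. Those genes flagged the array, so they cannot decide. Across genes the OT15 WD-SCC array correlated at 0.950 with the OT14 WD-SCC array and at 0.909 and 0.928 with the OT7 WD-SCC arrays. Cells from outside the 3 lineages and loss of the inactive X chromosome stay open and were not tested.

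The fall of epithelial genes in PD-SCC was set against brighter nonspecific background on the WD-SCC arrays. Of all 85 measured genes of the 3 epithelial lists, 53 (62.4%, exact 95% interval 51.2% to 72.6%) had a difference under -1.44. That was the difference of the nonspecific control that fell furthest. Under -1.77, the lowest of a control in any lineage, lay 49, which argues against background as the cause for those genes. Intervals over the genes of a list take the genes as independent, while such genes can vary together, so the intervals may be too narrow. Fibroblasts could stand in place of epithelial cells, although the cells were sorted for α6-integrin. A smaller share of epithelial cells would raise all fibroblast markers. In OT7 5 of 24, Fbln1, Gpx3, Dpt, Clec3b and Serpinf1, were lower and only Crabp1 higher (limma, adjusted over the list alone). Those 5 falls argue against fibroblasts there, while fibroblasts of a changed kind stay open. The list's median in OT7 does not decide by itself, at -0.48 (95% interval -2.34 to 0.24). By size alone 11 markers fell and 4 rose by over 1 there. Fibroblasts may have contributed in OT14, which has 1 array per stage and where the list's median was 0.55 (95% interval 0.08 to 2.29). There Col1a1, Col3a1 and Dcn stood at 5.64, 3.54 and 7.75 in WD-SCC and at 10.03, 9.76 and 10.04 in PD-SCC. On the OT7 WD-SCC arrays the same genes averaged 10.36, 9.50 and 10.14. Lum, Mfap5, Sfrp2, Fap and Dpp4 lay between 2.95 and 3.20 on the OT14 PD-SCC array. In OT15 the median of -0.25 (-0.45 to 0.89) does not decide. There 6 markers fell and 5 rose by over 1, and with 1 array per stage none was called lower. The stage itself, which the design names, stays open as the biological explanation.

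Of 27 haematopoietic markers 7 and of 21 endothelial and pericyte markers 5 were lower in PD-SCC, although the suspensions had been depleted of such cells, and neither list's call held with an estimated correlation (adjusted p = 0.25 and 0.404 with an estimated correlation). Background stays open for the lists as a whole. Of all 48 measured markers 13 had a difference under -1.44, that of the control that fell furthest. The median of the 48 was -0.77 (95% interval -1.22 to -0.42, with the genes taken as independent). Among the 12 markers called lower 9 were under -1.44 and the median was -2.41, but these were picked for falling. Endothelial cells left in the WD-SCC sort may account for part. Of 8 general endothelial genes 4, Pecam1, Cdh5, Tie1 and Egfl7, lay above the bacterial controls on all 4 WD-SCC arrays, although Tek was under them on each. Cdh5 and Egfl7 lay above them on all 4 PD-SCC arrays too, Pecam1 on 3 and Tie1 on 0. Their detection was thus mostly not particular to WD-SCC, but their levels were lower in PD-SCC. The WD-SCC and PD-SCC means were 7.31 and 3.49 for Tie1 (limma adjusted p = 0.0153) and 6.08 and 4.13 for Egfl7 (adjusted p = 0.0443). Short of the threshold they were 6.50 and 3.84 for Pecam1 (adjusted p = 0.0531) and 8.08 and 5.54 for Cdh5 (adjusted p = 0.177). For haematopoietic cells 3 of 10 general leukocyte genes, Fcer1g, Cd52 and Cd74, lay above the controls on all 4 WD-SCC arrays (Fcer1g mean 7.74). Fcer1g and Cd74 did so on all 4 PD-SCC arrays too, and Cd52 on 3. Ptprc lay under the controls on every array (WD-SCC mean 3.10), and 3 of 10 genes are too few to decide. A change of the tumour cells with stage was not tested.

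Gene lists differed in their stage effect between lineages in 20 of 69 tests of the difference (camera with the preset correlation, adjusted over the 69), and 0 of 69 held with an estimated correlation. Median effects in OT14 minus those in OT7 were -1.64 for the cornified envelope, -1.03 for epithelial identity, -2.16 for desmosomes and junctions, 0.80 for mesenchymal genes, 2.48 for extracellular matrix, 0.88 for matrix metalloproteinases, 1.24 for chemokines, -0.91 for endothelial markers and 1.04 for fibroblast markers. In OT15 minus OT7 they were -0.72 for epithelial identity, -1.35 for desmosomes and junctions, 2.72 for hemidesmosomes, 0.49 for matrix metalloproteinases and 0.24 for fibroblast markers. In OT15 minus OT14 they were 1.43 for the cornified envelope, 0.31 for epithelial identity, 2.01 for hemidesmosomes, -2.27 for extracellular matrix, 0.66 for endothelial markers and -0.80 for fibroblast markers.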

How the results depend on the processing

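The alternative settings of this part were chosen before the data were examined except the filter on a mean of at least 6 in the brighter stage and the interaction without lineage OT15 (0 genes, 1803 at an unadjusted p under 0.05), both chosen after seeing the data. Of 1640 values of the 75 named genes under other settings, 1291 kept their direction and side of the threshold, 339 lost the threshold, 9 gained it and 1 reversed, Dst at -0.0113 (adjusted p = 0.968) with the mean of a gene's probe sets. The tally repeats some fits, since leaving out either OT14 or OT15 array is the same as leaving out that lineage. It also counts the paired test, in which no gene passed, so it is no measure of robustness. The cause of these changes was not tested unless stated. The fit without the replicate block gave 2123 genes (1249 higher, 874 lower), 1708 of them shared, and the block moved no count of stage calls by over 1.5 times, though 8 named genes, Fst, Snai1, Loxl3, Pdgfc, Jag1, Mmp13, Adam8 and Pkm, lost the threshold without it (adjusted p from 0.0513 to 0.252).

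The 2154 genes past the threshold (1331 higher, 823 lower) became 401 (202, 199) with averaged OT7 arrays, which leaves fewer samples, 0 (0, 0) with the paired test on 3 lineage means (2574 at an unadjusted p under 0.05), and 3754 (2473, 1281) over all probe sets. Cyclic loess gave 799 higher genes, and a fold of at least 2 left 529 lower ones. Leaving out 1 array or lineage gave 247 to 1689 genes, 53 to 958 higher and 194 to 731 lower. The share of higher genes was 61.8% and became 46.2% with cyclic loess, 48.8% with the 75th percentile, 50.4% with averaged OT7 arrays and 21.5% without OT7. With a trended and robust prior OT14 gave 276 genes, OT15 361 and the interaction 14, and with the filter on dim genes OT15 gave 344. Leaving out 1 array gave 0 to 2 genes for the lineage difference. Itga6 ranged from -1.24 to 0.077 and Cd34 from 0.50 to 2.09 when 1 array was left out.

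The 2 higher lists became 1 with an estimated correlation, with fry and with the filter on a mean of at least 6, and the 7 lower became 1 with an estimated correlation. No called list was lost by leaving out 1 array. Camera's or fry's direction turned under some setting for 5 lists that had not been called. Without the replicate block camera pointed up for the hemidesmosome list, with its median unchanged at -0.27. Without 1 array that median was -0.96 to 0.031. Fry, which gives no median, pointed down for the hair follicle and hypoxia lists, where camera pointed up. Their medians in the main fit were -0.038 and 0.068. Camera pointed down for both with the filter on dim genes (medians 0.38 and -0.028) and with the filter at 6 (0.46 and 0.12). The hypoxia list had a median of -0.065 to 0.10 without 1 array. The fibroblast list had -0.0665 with the filter on dim genes and -0.45 to 0.10 without 1 array, and the interferon list -0.38 to -0.0066 without 1 array. Signal near the bacterial controls limits what can be said of dim genes.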

Other observations

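The count of genes between stages was set against other splits of the 8 arrays into 4 and 4. Of 35 splits 34 could be fitted with lineage as a block and 1 of the 34, the real one, gave as many as 2154 genes, the highest other giving 177. Of these, 22 do not part each lineage evenly, so that lineage and split overlap in them. The real split compares with the 12 that do, of which 1, the real one, gave as many and the highest other gave 0, and 12 splits are too few for a share under 0.05. For gene lists the splits could neither exclude chance nor show it. Of the 34 splits 14 called as many as the 9 lists of the real one, and the highest other called 13. Among the 12 even splits 5 did, with 12 as the highest other. The other even splits with 9 or more lists still set WD-SCC against PD-SCC in OT14 and in OT7 or OT15. Their calls can therefore carry the stage effect, so the count of lists does not measure chance.

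The neighbouring cell cycle inhibitor genes Cdkn2a and Cdkn2b, singled out after their values were seen, stood at 3.91 and 3.55 on the OT15 PD-SCC array, whose highest bacterial control was 3.81, while on the other 7 arrays they lay at 7.43 or more and 5.95 or more. Mtap, beside Cdkn2a, stood at 8.88 on that array. A loss of the 2 genes together may be one explanation, and it was tested, after those values had been seen, by counting neighbouring pairs of genes missing from an array but present on the other 7. With the bacterial control as the limit, Cdkn2a did not count as missing, and the 1 pair found was Psors1c2 and Cdsn (permutation p = 0.00980 over 10000 random gene orders, 0.0784 adjusted over the 8 arrays), so that test could not decide. The limit mattered: at 5%, 10%, 15% and 20% above the control, tried after the values were seen, the pair found was Cdkn2a and Cdkn2b, with permutation p of 0.0254, 0.0281, 0.0640 and 0.132. Neither gene was past the threshold in the test of a difference between the lineages' stage effects (adjusted p = 0.181 and 0.247).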
